A study of Mus musculus with 2 samples.

How the data were processed

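Total RNA of NIH3T3 cells infected with a control or a CCR4b hairpin retrovirus was measured on Affymetrix GeneChip Mouse Genome arrays, a 1-colour platform on which each transcript is read by sets of short probes. There were 2 arrays, 1 per group, and the groups were taken from the knockdown label. Per the labels' protocols, RNA was extracted with ISOGEN, purified on RNeasy columns and turned into biotin-labelled cRNA. The deposited values are probe-set intensities on a linear scale. Per the series design text, the authors computed them in GCOS and applied a global normalization. GCOS is also the only tool in the submitters' processing notes. Its version, the target value of the normalization and detection calls are not given in the sources used here. The upper quartile was 35.9 units on the control array and 35.8 on the CCR4b RNAi array, and all values were above 0, with maxima of 5962 units (control) and 5670 units (CCR4b RNAi). Array number limits the precision: with 1 array per group there is no replicate error, no p-value and no way to separate the effect of the hairpin from any other difference between the dishes.

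Genes were named through the platform annotation, in which 34958 probe sets have 1 gene symbol, 932 have several and 9211 are not listed and so are unnamed here. Of those with 1 symbol, 34754 matched a gene of the GRCm38.p6 RefSeq table, and 0 symbols changed. Only probe sets with 1 symbol entered the gene analysis. No coordinates are given because the files name no genome build.

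Signals were used as deposited, raised to a floor and turned into log2 ratios of CCR4b RNAi over control RNAi. The floor was the 50th percentile of all values of both arrays, 8.07 units, because the table holds no detection calls. A gene was measured if the brighter array reached the floor. The probe set with the highest mean log2 signal stood for its gene. A gene below the floor on 1 array has a ratio against the floor, which is a bound and is written as "at least". The spread around a gene's ratio is the robust SD (scaled median absolute deviation) of log2 ratios in its class of mean signal, from 10 equal classes. It contains real differences between cultures as well as measurement error. Probe sets with identifiers ending in _x_at or _s_at can hybridise to several transcripts.

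For 32 gene lists, holding 848 entries of which 774 have a probe set of their own, the median log2 ratio of the measured members was set against 10000 random lists of the same size drawn from the same signal classes. The shift is the list's median minus the median of the random lists. A list was said to stand apart where its percentile was under 2.5 or over 97.5. This held for 17 lists, 10 above and 7 below, where 1.6 would if genes varied independently. Genes of one process do not, and some lists share members, so more lists than that could stand apart between any 2 cultures. The lists, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the CCR4-NOT and CDK inhibitor lists, the 12 highest and 12 lowest ratios among genes above the floor on both arrays without an opposing probe set, up to 4 bounds per direction, up to 2 members per direction and list with at least a 1.5-fold difference, and Actb and Gapdh. A gene that several parts of the rule name counts under each. Random seeds were fixed.

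The procedure was tested on simulated data made from the control array, with noise taken from probe sets of the same gene and 200 genes, all well above the floor, changed by known amounts. In this simulated comparison of CCR4b RNAi over control RNAi, the 2-fold threshold recovered 96 of 100 genes changed by 1.5 log2 units and 99 of 100 genes changed by 2 log2 units among 11645 genes, and 149 of 11445 unchanged genes passed it. Of 1000 unchanged lists of 25 genes, 54 stood apart, and all 1000 lists raised by 0.5 log2 units did. The unchanged lists were drawn at random with independent noise, so a rate near that of the thresholds was built in. They do not show how often genes of one process would stand apart between cultures that differ in other ways. The noise was drawn from a normal distribution with a robust SD from probe sets above the floor on both arrays. It leaves out variation between cultures, outlying probe sets and the added noise of dimmer signals, so the recovery is a best case.

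RNA quality was checked on the 3' and 5' control probe sets. The 3'/5' signal ratio of Actb was 1.35 in the control and 1.46 after CCR4b RNAi, and that of Gapdh was 0.824 and 0.819. It was 3.34 and 2.88 for Pcx and 0.188 and 0.346 for 18S, a ribosomal RNA without a poly(A) tail, a change of 0.88 log2 units. The alternatives were scaling by the array median, quantile normalization, a loess correction of the ratio on signal (span 0.3), floors at the 25th and 75th percentile, no floor with log2 of signal plus 1, the median over a gene's measured probe sets, leaving out _x_at and _s_at probe sets, and thresholds of 1.5-fold and 3-fold. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.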

Results

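Messenger RNA levels were compared between 2 cultures of NIH3T3 cells, an immortalised mouse embryonic fibroblast line. One culture had received a retrovirus expressing a short hairpin RNA against CCR4b, also called CNOT6L, and the other a control RNAi virus. CCR4b is a catalytic deadenylase subunit of the CCR4-NOT complex, which shortens the poly(A) tails of mRNAs. The comparison asks which transcripts differ when this deadenylase is depleted. Each group holds 1 array, so no value below has a replicate error and no test across arrays was possible. "Higher" and "lower" describe this pair of arrays only. The CCR4b RNAi array is always set over the control RNAi array.

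The 45101 probe sets had a median signal of 7.81 arbitrary units on the control array and 8.34 on the CCR4b RNAi array. Of the 18194 genes with a probe set of their own, 11915 reached the floor of 8.07 units on at least 1 array, and 10060 did so on both. Across the 19759 probe sets above the floor on both arrays, log2 signals correlated with a Pearson r of 0.956, a value across probe sets, which are not independent replicates. The median log2 ratio of the measured genes was -0.070, with a robust SD across genes of 0.49. Genes in the brightest of 10 signal classes had a median log2 ratio of -0.17, whereas class 3, of dim genes, had 0.077. The 18 hybridisation spike-in probe sets had a median log2 ratio of -0.022 (SD 0.092 across probe sets), and the 24 poly-A spike-in probe sets had 0.13 (SD 0.16). Different probe sets of one gene differed with a robust SD of 0.30 log2 units per probe set over 4550 genes. Where the brighter of them showed at least a 2-fold difference, the other had the same sign in 287 of 323 genes.

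Cnot6l, the targeted gene, was lower in the CCR4b RNAi culture on each of its 4 probe sets. The brightest probe set read 102 units in the control and 43.0 after CCR4b RNAi, which is 2.38-fold lower (log2 ratio -1.25). This ratio lay at percentile 2.35 of genes of similar signal, which had a robust SD of 0.50. The next probe set read 29.0 and 10.3 units, and the remaining pair passed below the floor in the depleted culture. Cnot6, which encodes the closely related deadenylase CCR4a, was also lower on all 4 of its probe sets, with log2 ratios of -0.69, -1.03, -0.80 and -0.85. Among 690 genes with at least 4 probe sets above the floor, 9 had every probe set at or below -0.69. That cut is the least negative Cnot6 value, and genes with more probe sets had to pass it more often, so the count is no test. The other deadenylase pair of the complex differed little. Cnot7 had a log2 ratio of -0.14 and Cnot8 of -0.30, within the robust SD of 0.44 among genes of similar signal. Of the other subunits, Cnot11 was 1.53-fold lower (log2 ratio -0.62), and Cnot3 was 1.84-fold lower on its brighter probe set but had a log2 ratio of 0.27 on its dim one. Cnot2 had log2 ratios of -0.19, 0.24, -0.34 and -0.30 on its measured probe sets, all but that at -0.34 open to cross-hybridisation. Cnot4 had 0.18, 0.32, 0.26 and 0.22, and -0.070 on its dimmest probe set. The Tnks1bp1 log2 ratio was -0.11, which turned to 0.0051 with quantile normalization. Cnot9 had 0.046, which turned to -0.048 when each array was divided by its median. Cnot10 had -0.42 on its brightest probe set but 0.28 and 0.31 on dimmer ones. As a list, the 11 measured subunits did not stand apart from random lists of genes of matched signal (shift of the median -0.16 log2 units, percentile 17.5 of 10000 random lists).

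**Figure D1:**
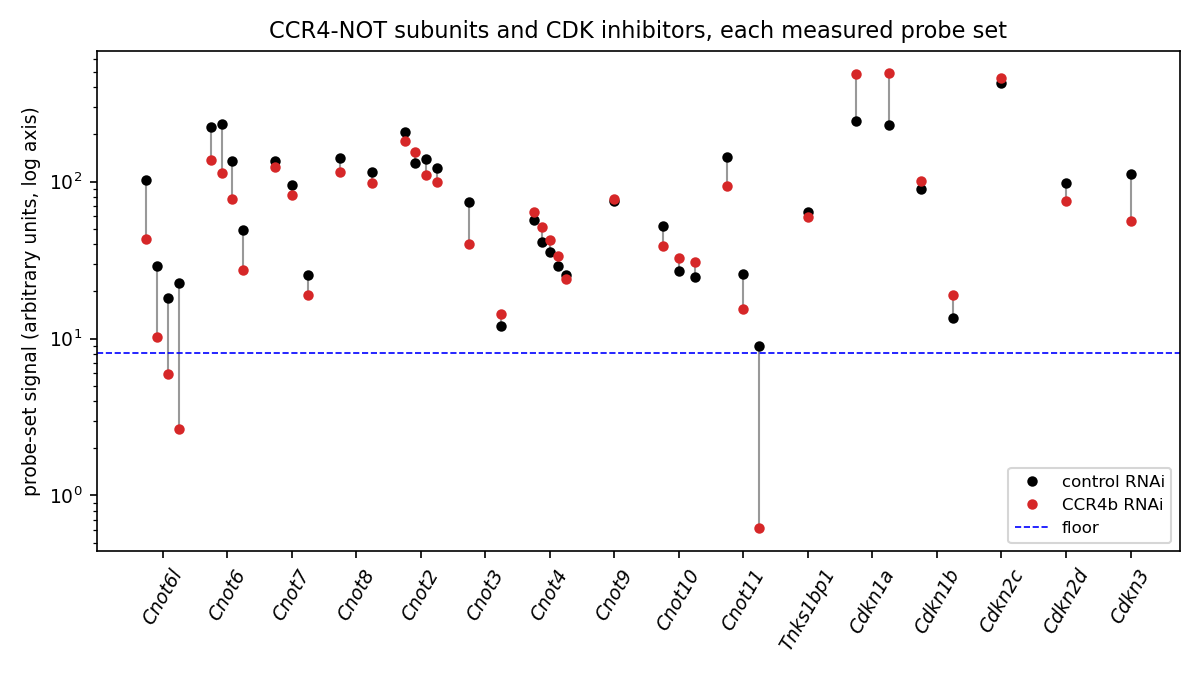
Probe-set signal (arbitrary units, log axis) of CCR4-NOT subunits and CDK inhibitors in the control RNAi array (black) and the CCR4b RNAi array (red), with a line joining the values of each measured probe set and the floor dashed. All 4 Cnot6l and all 4 Cnot6 probe sets were lower after CCR4b RNAi, and both Cdkn1a probe sets were higher.

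Other factors of mRNA turnover were lower as a group. The list of other deadenylases and decay factors had a shift of -0.29 log2 units, where 95% of matched random lists lay between -0.19 and 0.19, and 12 of its 37 measured members were at least 1.5-fold lower against 0 as much higher. The largest differences were those of Dis3, a catalytic subunit of the RNA exosome (2.40-fold lower, log2 ratio -1.26), and Exosc8, an exosome core subunit (2.21-fold lower, but 28.0 and 30.1 units on a dimmer probe set). The shift of this list lay inside the random range when probe sets open to cross-hybridisation were left out (-0.16). The BTG/TOB family and 3' UTR binding proteins shifted by 0.24 (percentile 98.3), came back inside the random range under 2 of 8 alternatives and went both ways, with 3 of 26 at least 1.5-fold higher and 3 as much lower. Cpeb1 was 2.75-fold higher from 10.6 units, Zfp36, which encodes tristetraprolin, was 1.62-fold higher, and Nanos1 was 2.68-fold and Hnrnpd 1.83-fold lower.

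The inhibitors of cyclin-dependent kinases did not move together. Cdkn1b encodes p27, the inhibitor that published work on CCR4b depletion in these cells followed. Its brighter probe set read 89.2 units in the control and 101 after CCR4b RNAi, 1.13-fold higher (log2 ratio 0.18), which is less than the robust SD of 0.43 among genes of like signal. Its dimmer probe set went from 13.6 to 18.9 units, 1.39-fold higher. Cdkn1a, which encodes p21, was higher on both probe sets, from 244 to 481 units (1.97-fold) and from 228 to 488 units (2.14-fold). Cdkn3, a phosphatase that acts on CDKs, was 1.99-fold lower. Cdkn2c and Cdkn2d had log2 ratios of 0.11 and -0.37, and Cdkn2b passed from 9.40 units to below the floor. The list shift was 0.068 (percentile 64.6, 6 genes). Regulators of p27 shifted by 0.066 (percentile 68.7). Among them Cks1b, a cofactor of the ubiquitin ligase that degrades p27, was 2.08-fold lower, Cops5 was 1.51-fold lower, and Foxo3, a transcription factor, was 1.67-fold higher. G1 cyclins, CDKs and RB/E2F genes shifted by -0.25 (percentile 3.60, inside the 95% range). E2f7 was 3.04-fold and Rbl1 2.43-fold lower, while Rb1 was 2.08-fold higher from 13.5 units.

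At a threshold of 2-fold, 446 of the 11915 measured genes were higher after CCR4b RNAi and 534 were lower. Of these, 335 higher and 472 lower genes were above the floor on both arrays. Simulated noise taken from probe sets of the same gene gave 149 such genes of either direction among 11445 unchanged genes. That noise was drawn from a normal distribution with a robust SD from probe sets above the floor on both arrays. It leaves out variation between cultures, outlying probe sets and the added noise of dimmer signals, so 149 does not cover all measurement noise. Among genes above the floor on both arrays, the highest ratio was that of Hp, which encodes haptoglobin, at 12.7 and 139 units (log2 ratio 3.46). It was followed by Prelp, a small leucine-rich proteoglycan (9.25-fold, with 5.82-fold on its second probe set). Further genes at the top were Gas6, a ligand of TAM receptor kinases first described in growth-arrested fibroblasts (6.59-fold), Aldh1a7, an aldehyde dehydrogenase (5.86-fold, from 260 to 1524 units), Abca1, the cholesterol efflux transporter (5.82-fold), Ogn, the proteoglycan osteoglycin (5.16-fold and 5.86-fold on its pair of probe sets), and Depp1 (5.15-fold, with a log2 ratio of at least 4.20 on its second probe set). Abca1 differed between probe sets, with 2.49-fold and 1.02-fold on its dimmer ones. Speer4b, Gpr135, Nbl1, Itgb8 and Plscr2 completed the 12 highest, with ratios between 4.72-fold and 7.95-fold from control signals of 8.47 to 10.3 units, close to the floor. Speer4b belongs to a multigene family. The brightest probe sets of Gpr135 and Prelp are open to cross-hybridisation, as are those of Cnot7 above and of Aurkb, Adm and Epcam below. The second probe sets of Prelp (5.82-fold) and Adm (2.75-fold higher) are not of that kind. Gpr135 read 5.23 and 22.4 units on its second probe set and stayed below the floor on both arrays on its dimmest. Timp4, a metalloproteinase inhibitor, was below the floor in the control and read 83.5 units after CCR4b RNAi, at least 10.3-fold higher. Aspn and Mgam were at least 5.99-fold and Gpnmb at least 5.82-fold higher by the same bound.

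Among genes above the floor on both arrays, the lowest ratios included several genes of DNA replication, repair and chromosome segregation. Brca1, a DNA repair gene, was 4.32-fold lower, Ska1, a kinetochore subunit, 4.31-fold, Cdc6, a replication licensing factor, 4.10-fold, and Pole, the catalytic subunit of DNA polymerase epsilon, 3.97-fold lower. Brca1 had a log2 ratio of -0.76 on the median of its probe sets, and a dim one read 13.6 and 13.2 units. Mthfd2, a mitochondrial folate enzyme, was 4.10-fold lower and Fdps, farnesyl diphosphate synthase, 4.02-fold lower, from 1152 to 287 units. Cdsn (4.60-fold), Mrpl43, a mitochondrial ribosomal protein (4.58-fold), Pam (4.47-fold), Cep89 (4.38-fold, but 1.10-fold on a dimmer probe set), Hirip3 (4.16-fold) and Mtfr2 (3.98-fold) were the others of the 12 lowest. Of these 12, Pam, Mtfr2, Cep89, Cdsn and Cdc6 read 8.35 to 10.1 units after CCR4b RNAi, close to the floor. Oip5, a centromere protein, read 53.8 units in the control and was below the floor after CCR4b RNAi, at least 6.67-fold lower. Car6, Atp8b4 and Prorp were at least 5.37-fold, 4.21-fold and 3.76-fold lower by the same bound.

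**Figure D2:**
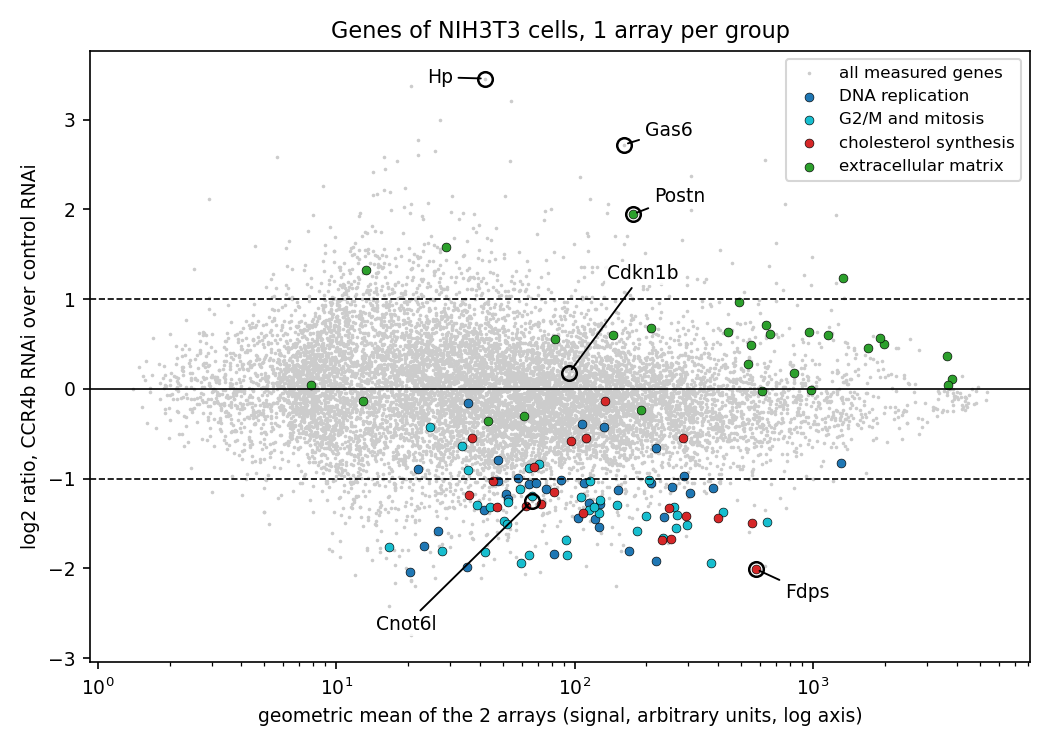
Log2 ratio of CCR4b RNAi over control RNAi against the geometric mean signal of the 2 arrays (arbitrary units, log axis) for the 11915 measured genes, values below the floor being raised to it in the ratio, with members of 4 gene lists coloured, 6 genes circled and named and dashed lines at 2-fold. Replication, mitosis and cholesterol synthesis genes lie below 0 across the signals that they span, which do not reach the dimmest or the brightest measured genes.

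Genes of cell division were lower after CCR4b RNAi. Of 36 measured DNA replication genes, 27 were at least 2-fold lower and 0 were 2-fold higher, and the list shifted by -0.999 log2 units (2.00-fold) relative to genes of like signal, where 95% of random lists lay between -0.19 and 0.18. Of 37 G2/M and mitosis genes, 32 were at least 2-fold lower and 0 were 2-fold higher, with a shift of -1.25 (2.38-fold). Both shifts were below those of all 10000 random lists. Each of the 73 genes in these lists lay below the median of its signal class. Examples beyond Cdc6 and Pole were Mad2l1, a spindle checkpoint protein, at 732 and 190 units (3.84-fold lower), and Aurkb, a mitotic kinase (3.84-fold lower). Random lists treat genes as independent, and genes of one process are not, so these percentiles describe the pair of arrays and are not p-values.

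Several metabolic programmes differed in the same pair of arrays. Of 20 measured cholesterol synthesis genes, 14 were at least 2-fold lower and 0 were 2-fold higher, with a shift of -1.15 (2.22-fold, below all random lists). Besides Fdps, Cyp51, the lanosterol demethylase, was 3.21-fold lower, from 415 to 129 units. Targets of ATF4 and the amino acid response shifted by -0.66 (1.57-fold), with 10 of 29 at least 2-fold lower and 0 at least 2-fold higher. At 1.5-fold, 17 were lower and 1 was higher. Mthfd2 and Slc7a5, an amino acid transporter (3.37-fold lower), led them. Oxidative phosphorylation genes shifted by -0.32, with 14 of 43 at least 1.5-fold lower and none 1.5-fold higher, led by Cox6a1 (1.91-fold) and Atp5g1 (1.86-fold). Glycolysis and hypoxia genes went the other way, with a shift of 0.50 (1.42-fold, above all random lists), and 8 of 22 were at least 1.5-fold higher against 0 as much lower. Adm, which encodes adrenomedullin, was 3.17-fold higher and Bnip3, a mitophagy receptor, 2.29-fold higher. ER chaperones and unfolded protein response genes shifted by -0.23 (percentile 2.00), 5 of 21 at least 1.5-fold lower and 1 as much higher, with Pdia4 1.79-fold and Manf 1.76-fold lower. Atf6 was 2.53-fold higher on its brightest probe set but not on its other probe sets, where it had log2 ratios of -0.23 and -0.14. The ER list returned inside the random range under 6 of 8 alternatives. Heat shock and oxidative stress genes did not stand apart (shift -0.082, percentile 22.3). In that list the metallothioneins Mt2 and Mt1 were 2.27-fold and 2.01-fold higher, and Gclc and Gsta4 were 2.15-fold and 1.75-fold lower, with Gclc at a log2 ratio of -0.27 on its dimmer probe set. The Mt1 probe set is open to cross-hybridisation, and without it the log2 ratio was -0.048, from a probe set at the floor.

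Lists of matrix and signalling genes of fibroblasts were higher in their medians. Extracellular matrix genes shifted by 0.64 (1.56-fold, above all random lists), with 12 of 29 at least 1.5-fold higher and none as much lower. Postn, which encodes periostin, was 3.85-fold higher, from 89.5 to 345 units, and Col11a1 2.99-fold. Matrix proteases and inhibitors shifted by 0.31 (percentile 99.4), with 7 of 20 at least 1.5-fold higher and 1 as much lower, among them Adamts5 2.54-fold and Ctsk, cathepsin K, 2.45-fold higher and Mmp9 2.10-fold lower on its brighter probe set but 1.27-fold higher on its dimmer one. Growth factor receptors and ligands shifted by 0.51 (1.42-fold), with 9 of 23 at least 1.5-fold higher and 1 as much lower. Igf2 was 2.56-fold higher beside Gas6, whereas Axl, a receptor for GAS6, was 2.24-fold lower. TGF-beta and BMP targets shifted by 0.31 (percentile 99.2) and went both ways, with 5 of 22 at least 1.5-fold higher and 2 as much lower. The latent TGF-beta binding proteins Ltbp2 and Ltbp1 were 2.57-fold and 2.51-fold higher, and Id4 was 2.06-fold lower on its brightest probe set and 1.37-fold on the next. Cytokine and inflammation genes shifted by 0.25 (percentile 98.7), with 4 of 22 at least 1.5-fold higher and 1 as much lower. Cxcl12, a chemokine, was 3.84-fold higher on its brightest probe set, from 635 to 2438 units, and 1.28-fold on another bright one. Ccl8 was 2.22-fold higher and Ptgs2, cyclooxygenase 2, 1.69-fold lower. The cytokine list returned inside the random range under 4 of 8 alternatives. Actin cytoskeleton genes did not stand apart (shift 0.090, percentile 78.4). Zyx, which encodes zyxin, was 2.44-fold and Csrp1 1.57-fold lower, and Myl9 was 1.54-fold higher.

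Interferon response genes shifted by 0.51 (1.43-fold, percentile 99.98). Of 24 measured, 10 were at least 1.5-fold higher and 1 was at least 1.5-fold lower, and 4 lay below the median of their signal class. Among members above the floor on both arrays, the highest ratios were those of Ifit3, from 11.1 to 28.4 units (2.57-fold), and Gbp3, from 10.5 to 23.1 units (2.21-fold). Igtp, below the floor in the control, read 27.1 units after CCR4b RNAi (log2 ratio at least 1.75). The leading members were thus dim. Both cultures carried an RNAi virus, and 1 array stands for each.

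Targets of p53 and growth arrest genes shifted by 0.24 (percentile 98.4). Zmat3, a p53-induced zinc finger gene, was 4.32-fold higher, from 56.0 to 242 units, and Gas2 was 2.05-fold higher, while 21 of the 25 genes lay within 1.5-fold. BCL2 family and caspase genes shifted by 0.30 (percentile 99.2), 4 of 21 at least 1.5-fold higher and 1 as much lower, with Bnip3 and Bcl2l2 (1.54-fold) higher and Casp2 1.64-fold lower. The other higher genes, Bcl2 and Casp9, were below the floor in the control and read 26.0 and 15.8 units after CCR4b RNAi, so their ratios are bounds. Each of these lists came back inside the random range under 1 of 8 alternatives. Senescence-associated genes did not stand apart (shift -0.050, percentile 35.6), with Hmgb2 1.81-fold and Igfbp4 1.58-fold lower. One Igfbp4 probe set, open to cross-hybridisation, was 1.34-fold higher. Immediate early genes, many of which encode short-lived mRNAs, did not stand apart either (shift 0.047, percentile 68.7). Myc and Klf2 were 2.14-fold lower, whereas Egr1 was 1.99-fold and Junb 1.63-fold higher.

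Markers of other cell types were mostly below the floor on both arrays, and none of their lists stood apart. The shift was 0.076 for adipocyte markers (6 of 15 measured), 0.074 for muscle markers (5 of 17), -0.023 for cartilage and bone markers (6 of 14), -0.13 for blood and macrophage markers (5 of 16) and -0.057 for epithelial and endothelial markers (3 of 18). Lpl, lipoprotein lipase, was 4.15-fold higher, from 374 to 1554 units, while Scd1 and Fasn of the same adipocyte list were 1.79-fold and 1.53-fold lower. Cd68 was 2.55-fold lower and Cd14 1.79-fold higher. Tnnc1 and Epcam were 1.70-fold and 1.52-fold higher, and Ckm and Alpl 1.57-fold and 1.55-fold lower, all from control signals of 8.64 to 19.4 units. Cytosolic ribosomal protein genes did not stand apart (shift -0.020, percentile 40.9, 36 genes). Rps25 (291 to 115 units) and Rpl14 (132 to 75.8 units) were 2.53-fold and 1.74-fold lower and Rps27 (39.1 to 69.2 units) 1.77-fold higher. These probe sets were dim beside that of Rpl4, at 4666 units in the control, and whether they read the main transcripts was not tested. Among the 13 measured reference genes (shift 0.068, percentile 69.0), the Actb log2 ratio was -0.11, but 0.088 on the dimmest probe set, and it turned to 0.049 after the loess correction. The Gapdh log2 ratio was -0.075, which turned to 0.085 after that correction and to 0.021 with quantile normalization. Tfrc, the transferrin receptor, was 2.99-fold lower and Polr2a, the large subunit of RNA polymerase II, 2.01-fold lower.

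**Figure D3:**
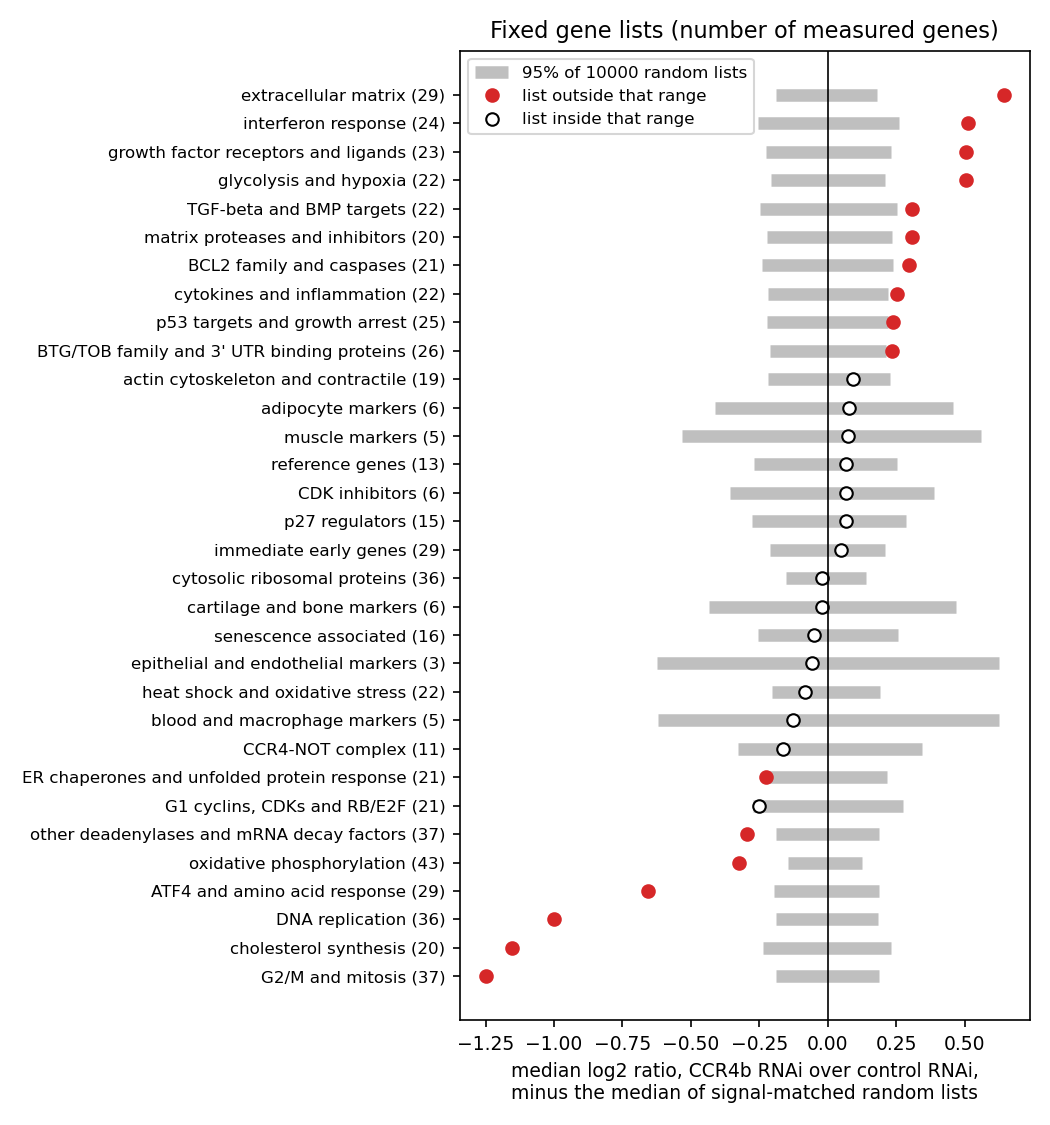
Shift of the median log2 ratio (CCR4b RNAi over control RNAi) of each of the 32 fixed gene lists relative to the median of signal-matched random lists, with the number of measured genes in brackets, grey bars for the range of 95% of 10000 random lists and filled points for lists outside it. The list furthest below 0 is G2/M and mitosis at -1.25 and the furthest above is extracellular matrix at 0.64.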

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

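The comparisons planned did not include the probe sets described here, whose ratios were looked at after those of the named genes. A signal outside the gene analysis was looked for among the 10092 probe sets that carry no single gene symbol, apart from the control probe sets. Of the 2195 above the floor on both arrays, 97 were at least 2-fold higher after CCR4b RNAi and 65 at least 2-fold lower. The highest ratios were 3.89 on the log2 scale (25.2 and 374 units, a probe set open to cross-hybridisation), 2.65 (9.48 and 59.5 units) and 2.31 (from 9.05 units). The first of these exceeded the ratio of every named gene measured on both arrays by its brightest probe set. Their genes are not named here.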

How the results depend on the processing

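None of the alternatives here was chosen after a result was seen. No paired analysis was possible because each group holds 1 array, and for the same reason no replicate could be left out. The number of genes past the threshold depended on the floor. Against 446 genes at least 2-fold higher in CCR4b RNAi and 534 genes at least 2-fold lower in CCR4b RNAi, a floor at the 25th percentile gave 1787 and 1791, a floor at the 75th percentile 126 and 265, and no floor 2009 and 2048. A 1.5-fold threshold gave 1352 higher and 1744 lower genes, and a 3-fold threshold 86 and 92. The scalings kept both counts within 1.5 times, and the median log2 ratio of all measured genes lay between -0.16 (arrays divided by their medians) and -0.018 (loess). The Cnot6l log2 ratio stayed between -1.36 and -1.16 and the Cdkn1b log2 ratio between 0.086 and 0.33. The 75th percentile floor left no value for muscle markers or for epithelial and endothelial markers. Over 254 list values under alternatives, 224 stayed on their side of the random range and within its SD. A further 15 moved by more, 15 came back inside the range, and 0 changed sign while standing apart. In all, 13 of the list values, from 5 lists, changed sign. The scalings change genes of like signal together, so they test shifts relative to such genes only weakly. The shifts of replication (-1.08 to -0.94), mitosis (-1.25 to -1.17) and extracellular matrix genes (0.62 to 0.72) stood apart under all 8 alternatives, as did cholesterol synthesis, which moved to -1.02 with the median of probe sets. The decay factors moved to -0.19 with the median of probe sets but still stood apart, and came back inside the range without _x_at and _s_at probe sets (-0.16). BTG/TOB and 3' UTR binding proteins came back with the median of probe sets (0.14) and without _x_at and _s_at probe sets (0.15). So did p53 targets with the median of probe sets (0.12) and the BCL2 family without _x_at and _s_at probe sets (0.18). Cytokines did so with quantile normalization (0.16), loess (0.20), the 25th percentile floor (0.16) and no floor (0.14). ER chaperones did so with loess (-0.19), the 25th and 75th percentile floors (-0.21 and -0.22), no floor (-0.22), the median of probe sets (-0.10) and without _x_at and _s_at probe sets (-0.16). ATF4 targets moved to -0.54 with the 75th percentile floor and -0.55 without _x_at and _s_at probe sets, and matrix proteases to 0.43 with the 25th percentile floor, all standing apart. Lists that never stood apart moved as follows: CDK inhibitors to -0.14 and 0.29 with the 25th and 75th percentile floors, adipocyte markers to -0.15 with no floor, muscle markers to 0.53 with the 25th percentile floor, cartilage and bone markers to 0.54 with the 75th percentile floor, blood markers to 0.34 without _x_at and _s_at probe sets, and epithelial and endothelial markers to -0.64 with the 25th percentile floor. This held for a further list: immediate early genes moved to -0.087 with the 25th percentile floor, -0.086 with no floor and -0.061 with the median of probe sets. Of 925 values of 118 other named genes, 873 stayed within the spread of their signal class, 50 moved by more, and 2 of genes with at least a 2-fold difference changed sign: Atf6 with the median of probe sets (-0.14) and Mt1 without _x_at and _s_at probe sets (-0.048). In all, 8 values changed sign, the others those of Gapdh, Actb, Cnot9, Cnot10 and Tnks1bp1, from smaller ratios. The cause of these moves was not tested, except that the higher floor by construction shrinks ratios of dim genes. Dim signals limit the genes that reach the floor on 1 array only, 1855 of those measured.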

Other observations

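The scan of gene families, the YAP, LXR and fatty acid lists, and the tests of signal dependence, RNA quality and blood cells were chosen only after results had been seen. The added lists were set before their own percentiles were known, but 5 of 14 measured YAP genes, 2 of 9 LXR genes and 2 of 14 fatty acid genes are also in planned lists, whose values had been seen. The families and the members of added lists named here were picked after their values were seen. Families were defined by the letters of the gene symbols, and 104 had at least 12 measured genes. Of these, 20 lay outside the range of 95% of matched random lists, 11 below and 9 above, where 5.2 would if genes varied independently. Mitochondrial ribosomal proteins were lower in both subunits, with a shift of -0.47 for 47 Mrpl genes and -0.37 for 29 Mrps genes, whereas the cytosolic ribosomal protein list had a shift of -0.020. Nucleoporins (Nup, 17 genes) shifted by -0.44 and eukaryotic initiation factors (Eif, 45 genes) by -0.19. On the higher side, collagens (Col, 25 genes) shifted by 0.40 and clustered protocadherins of the beta group (Pcdhb, 13 genes) by 0.50. Many of the collagens are also in the planned extracellular matrix list, so their shift is not a separate result. Zinc finger genes (Zfp, 285 genes) shifted by only 0.12, but random lists of that size lay between -0.076 and 0.083.

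The first pattern is the lower level of replication and mitosis genes. A difference between the arrays that depends on signal alone is argued against, since median log2 ratios of the 10 signal classes lay between -0.17 and 0.077. The shift of -1.15 that these genes kept after the loess correction is no separate test. Random lists were already matched on signal, so the correction could change the shift little. Poorer RNA in one culture cannot be told apart. The 3'/5' ratio changed by 0.11 log2 units for Actb, -0.010 for Gapdh and -0.21 for Pcx. That of 18S, a ribosomal RNA without a poly(A) tail, changed by 0.88. A denser culture in the CCR4b RNAi dish cannot be told apart either: YAP targets, which density may lower, lay at percentile 90.5, but the bound of percentile 50 set beforehand against density was too lax and was tightened after the value was seen, because the shift of 0.20 lay inside the random range (-0.28 to 0.29) and members went both ways (9 higher, 5 lower, Axl at -1.16). Whether fewer cells were cycling, and whether through loss of CCR4b, lower Cnot6 or another difference between the dishes, was not tested, and a cell-cycle profile of replicate cultures would be needed.

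The second pattern is the lower level of cholesterol synthesis genes. One hypothesis is that they are part of a lower output of SREBP-driven lipid synthesis in general. Fatty acid synthesis genes, predicted to be lower if so, had a shift of -0.37 at percentile 0.56 of random lists. In that list 12 genes were lower (Acly at a log2 ratio of -0.84) and 2 higher (Acaca at 0.45). The 12 genes not in planned lists shifted by -0.33 (percentile 1.55). The prediction was met, but it does not single out SREBP. Among gene families, 11 lay below the random range and 9 above, and Mrpl (-0.47) and Nup (-0.44), outside lipid synthesis, were at least as low. Another is that the cells held more sterol, which would raise targets of the LXR receptors to which Abca1 belongs. The LXR targets other than Abca1 and Lpl, which share Scd1, Scd2 and Srebf1 with the fatty acid list, lay at percentile 54.5 with 9 genes measured, with members going both ways, which decides nothing.

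The third pattern is the higher level of interferon response genes. With the floor at the 75th percentile, the 11 genes left kept a shift of 0.40, above the random range that ended at 0.32. This argues against noise of signals near the floor for those brighter genes only. Among them, Psmb9 and Eif2ak2 reached that floor only on the CCR4b RNAi array, where they were higher. For the dimmer members that this floor removed, Ifit3 and Gbp3 among them, noise cannot be told apart. Blood or macrophage cells in the CCR4b RNAi culture cannot be told apart: 2 markers were higher, Lyz2 (from below the floor to 22.9 units) and Cd14 (log2 ratio 0.84), and Cd68 was lower (-1.35, close to the floor), and since 5 of the 16 markers were measured, the bound of 8 set for this explanation could not be reached. A response to the CCR4b hairpin virus itself, rather than to the loss of CCR4b, cannot be told apart from the depletion either, because the design holds 1 CCR4b RNAi array and no other hairpin against CCR4b was analysed here.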
